A study of Mus musculus and Homo sapiens with 13 samples.

How the data were processed

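The files hold 13 libraries: 5 TAF15 HITS-CLIP libraries of human temporal cortex, 2 TAF15 HITS-CLIP libraries of mouse neurons derived from embryonic stem cells, and 6 strand-specific RNA-seq libraries of such neurons, 3 with control siRNAs and 3 with TAF15 siRNAs. Groups and replicate numbers were taken from the labels. Per the labels, frozen human tissue was homogenized, irradiated with ultraviolet light, and treated with RNase T1 and DNase before immunoprecipitation with an anti-TAF15 antibody. For the mouse CLIP libraries the same antibody is named and the digestion is not given in the sources used here. RNA for RNA-seq was depleted of ribosomal RNA. Adapter trimming with cutadapt, alignment with BWA and the genome builds hg19 (human) and mm9 (mouse) are named in the submitters' processing notes without versions. How reads were grouped into regions, which mapping filters were used, and how multi-mapping reads and PCR copies were treated is not given in the sources used here.

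Each deposited file lists regions of 1 library with a strand and 2 whole-number counts. The deposited values were read as the count of all reads of a group of overlapping reads and the count of its most frequent read, an inference from the values, since no header states it. The second count never exceeded the first, and no 2 regions of a library overlapped on a strand. Regions were at most 76 nt wide in human and 101 nt in mouse files, the width of 1 read, so a region's position is that of 1 read while its count covers the whole group. This matters for every comparison, because a group of reads spread over a long transcript is recorded at a position that can differ between libraries. Coordinates are given 1-based in the build of the files. Human chromosomes X and Y were left out of every step to protect the donors.

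No genome or annotation of either build was used here. Consensus regions therefore took the place of genes, as fixed before the data were examined: overlapping regions of the 6 RNA-seq libraries on the same strand were merged and their counts summed. The check of the targeted gene, the gene lists, exon usage, annotation classes, target genes shared by human and mouse, and sequence motifs were planned and not run. Ribosomal, transfer and small nuclear RNAs could not be excluded from the named CLIP regions for the same reason, and mitochondrial regions were excluded.

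Knockdown and control were compared with edgeR 4.0.16 in R 4.3.3, with filterByExpr, TMM scaling, the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05, two-sided, without a replicate block. DESeq2 1.42.0 and limma 3.58.1 on log2(CPM + 1) were alternatives. The mitochondrial chromosome was kept in the fits of consensus regions and left out of the fits of windows described below. Standard errors were computed as the log2 fold change over the square root of the F statistic. After the consensus regions had been seen to vary strongly, reads were summed over 50-kb windows of 1 strand by the middle of each region, without short stacks. A short stack is a region under 25 nt whose most frequent read holds at least 10% of its reads. Short stacks made up 70.2% to 90.6% of the human regions, 22.0% and 22.5% of the mouse CLIP regions and 5.85% to 8.78% of the RNA-seq regions, where they held 2.10% to 4.35% of the reads. The window width, the removal of short stacks and all alternatives to them were chosen after the data were seen. Windows of 2, 10 and 200 kb, windows shifted by 25 kb, and minimum widths of 20 and 30 nt were also tried.

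CLIP regions of 2 libraries were called shared when they overlapped by at least 1 nt on the same strand. The share was set against the mean of 200 seeded circular shifts within each chromosome, and 95% Wilson intervals were computed. Alternatives required 5 reads or an overlap of 50% of the shorter region, left out brains in turn, or, added after the data were seen, left out regions with the same start and end as a region with at least 10 times the reads in another library. Bound windows were those with a CLIP region in both mouse libraries. Their change was tested with camera at a preset correlation of 0.01, with an estimated correlation, and against 10000 seeded random window sets matched on expression in 50 bins. All windows have the same length, so matching on length has no effect.

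The rule for named items was fixed before the data were examined. For CLIP, it takes the 10 regions with the highest mean share of a library's reads per species. For regions in place of genes, it takes the 5 largest changes per direction past an adjusted p of 0.05. The gene rule's further conditions, the same sign in all 3 same-numbered comparisons and a mean of at least 1 CPM, were carried over and met by all 543 called windows. Where no region passed, the 5 smallest p per direction were named and said not to pass. Stretches of 10-kb windows, runs of windows and short-stack sites were named after their values were seen.

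The scripts were tested on simulated data with known answers. The overlap count found all placed overlaps. In 30292 windows drawn from the means, library sizes and dispersions of the 50-kb windows, the knockdown test recovered 68% of 100 windows changed by a log2 fold of 1 and 24% of 100 changed by a log2 fold of 0.5, with 7 false calls among 99. In 30000 consensus regions drawn in the same way, it recovered 0 of 100 regions changed by a log2 fold of 3 and 0 of 100 changed by a log2 fold of 1. No pair of mouse libraries differed by so little as sampling noise allows, since the chi-square statistic per degree of freedom over 50-kb windows was at least 3.07. Copied reads also raise this statistic, so it cannot tell separate cultures from repeated libraries of 1 culture. Every library was counted as 1 replicate, as labelled. Principal components were computed on log2 CPM of the tested 50-kb windows. The verdicts on shared binding sites, on RNA shared within a brain, on the shallow library and on window borders were first written as exclusions. They were changed to undecided after the values were seen, since none of these tests could exclude its explanation. The test of opposite-strand sites was then also limited to other sites with a similar floor of reads. Analyses outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.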

Results

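TAF15 is an RNA-binding protein. The study asked which RNAs TAF15 binds in brain and neurons, whether that binding is conserved between human and mouse, and how the neuronal transcriptome responds to its loss. Binding was measured by HITS-CLIP, in which ultraviolet light crosslinks protein to RNA and the RNA fragments recovered with an antibody are sequenced. The 5 human CLIP libraries came from the temporal cortex of 3 brains. The labels name a main signal in brains 1, 2 and 3 and a higher signal in brains 2 and 3, and do not define these terms. The 2 mouse CLIP libraries came from neurons grown from embryonic stem cells. RNA-seq of the same type of mouse neurons, with ribosomal RNA removed, covered 3 libraries with control siRNAs and 3 with TAF15 siRNAs.

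Depth varied widely among the human libraries. The main-signal libraries of brains 1, 2 and 3 held 1122416, 4785207 and 251614 reads, and the higher-signal libraries of brains 2 and 3 held 4032431 and 1971686. The mouse CLIP libraries held 6844357 and 8561302 reads. The control RNA-seq libraries held 12361582, 12610694 and 13592267 reads, and the TAF15 siRNA libraries held 16022637, 5098996 and 13739699, so replicate 2 of the knockdown was the shallowest. In the human libraries 95.3% to 98.5% of the reads were copies of the most frequent read of their region, against 40.2% or less in the mouse CLIP libraries. Reads carried no molecular identifiers, so intervals on shares cover counting error only. Nothing in the labels states that libraries of 1 mouse group came from separate cultures, so p-values measure only the spread between these libraries.

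In human temporal cortex, the largest shares of CLIP reads lay on the plus strand of chromosome 11. No human input or RNA-seq library is in the files, so these shares do not separate binding from RNA abundance. Of the 10 regions with the highest mean share of reads, 9 lay between positions 65267497 and 65272582 (hg19), and each of the 9 had reads in all 5 libraries. The leading region, chromosome 11 from 65268235 to 65268261, held 0.439% ± 0.192 of a library's reads (SD, n = 5 libraries from 3 brains). The region from 65267614 to 65267645 followed with 0.0805% ± 0.0342. The remaining region of the 10 lay on chromosome 15, from 25456977 to 25457002 on the plus strand, with 0.0619% ± 0.0415 and reads in 4 of the 5 libraries. Summed over 10-kb windows, chromosome 11 from 65260001 to 65270000 held 0.853% ± 0.246 of the reads and the next window, to 65280000, held 0.373% ± 0.0729. These windows ranked 1 and 2 in all 5 libraries. The plus-strand windows of chromosome 15 from 25450001 to 25460000 (0.115% ± 0.0382), chromosome 14 from 101310001 to 101320000 (0.111% ± 0.0299) and chromosome 19 from 34880001 to 34890000 (0.0757% ± 0.0184) came next.

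In mouse neurons, the leading 10-kb window was chromosome 19 from 5790001 to 5800000 on the minus strand (mm9), with 3.47% ± 0.0187 of the reads (SD, n = 2). The adjacent window, to 5810000, held 0.278% ± 0.0133. The plus strand of chromosome 6 from 30750001 to 30760000 held 0.270% ± 0.000314. On the plus strand of chromosome 12, the windows that start at 110780001, 110790001 and 110800001 held 0.106% ± 0.00353, 0.196% ± 0.00286 and 0.204% ± 0.00474. On the minus strand of chromosome 7, the window that starts at 34990001 held 0.107% ± 0.000341 and the one that starts at 67020001 held 0.104% ± 0.003. Among single regions, chromosome 19 from 5802265 to 5802365 held 0.278% ± 0.0133 of the reads, and chromosome 12 from 110800800 to 110800867 held 0.0978% ± 0.00371. The position of a deposited region can move between libraries although its reads do not. In library 1 the largest region was chromosome 19 from 5796713 to 5796813 with 234145 reads, and in library 2 it was 5799124 to 5799224 with 290725 reads, while each of these had 0 reads in the other library. The mouse shares were not set against RNA-seq reads here, so they do not separate binding from RNA abundance either. No annotation of either build was used here, so these regions carry no gene names, and the comparison of target genes between human and mouse was not analysed here.

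CLIP regions were then compared between brains. Over the 6 ordered pairs of main-signal libraries, 14.1% ± 11.6 of the regions of 1 brain overlapped a region of another on the same strand, with a range of 1.88% to 34.3%. After circular shifts of the regions along each chromosome, the mean shares were 0.0391% to 0.377%, so that the observed shares were 48.0 to 190-fold higher. The shifts also place regions outside transcribed stretches. Libraries that share transcripts would exceed them without shared binding sites, so these folds do not measure shared binding. The highest share was that of brain 1 in brain 2 (34.3%, 95% Wilson interval 33.9 to 34.6), and the lowest that of brain 2, which had 464383 regions, in brain 3, which had 48265 (1.88%, 1.84 to 1.92). Of 792520 regions merged over the 5 libraries, 715078 (90.2%) were found in 1 library and 1047 (0.132%) in all 5. The numbers of regions in 50-kb windows gave rank correlations of 0.300 to 0.364 between human libraries, taken across windows, which are not independent replicates. When regions whose start and end equalled those of a region with at least 10 times the reads in another library were left out, the mean share was 6.04%, a setting chosen after the data were seen.

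**Figure D1:**
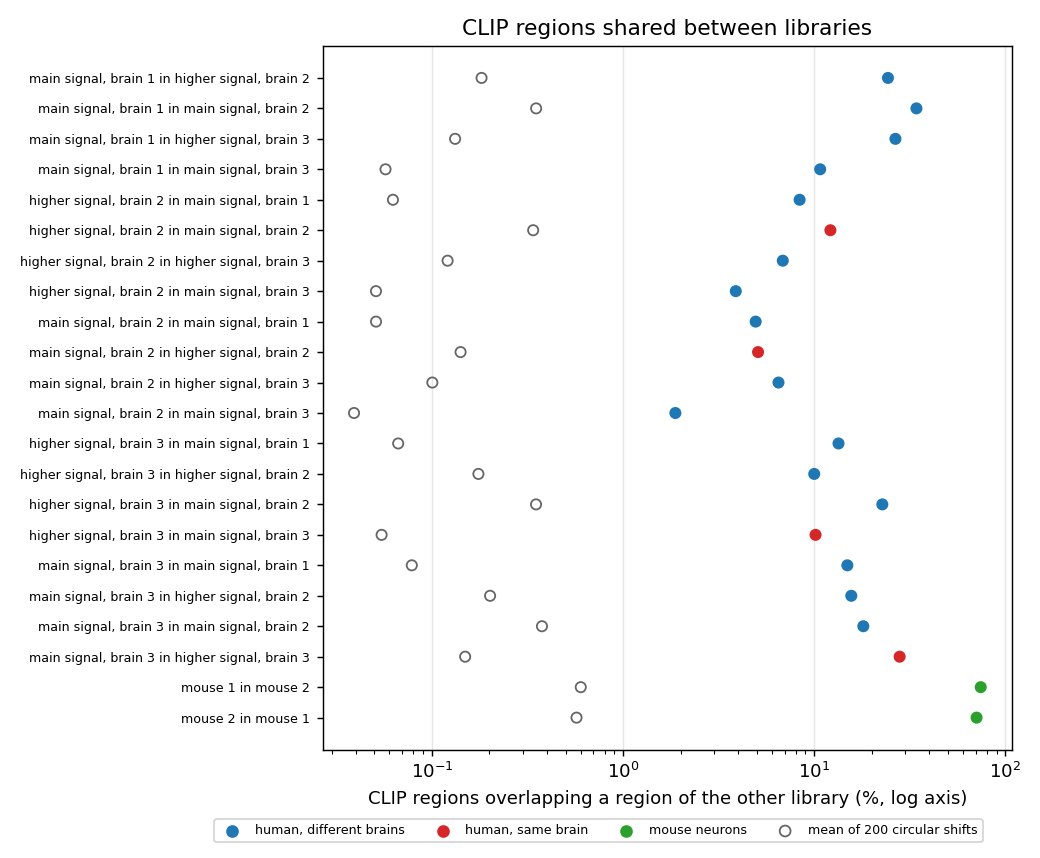
Share of the CLIP regions of 1 library that overlap a region of another on the same strand, on a log axis in percent. Filled points are observed shares and open points the mean of 200 circular shifts. The mouse pair lies at 74.3% and 70.7%, and the human pairs between brains at 1.88% to 34.3%.

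The higher and main signals were compared within brains 2 and 3. In brain 2, 12.2% of the higher-signal regions overlapped a main-signal region of the same brain (95% Wilson interval 12.01 to 12.30), against 3.89% for the main signal of brain 3. In brain 3 the order was the opposite, with 10.2% for the same brain (upper 95% Wilson bound 10.3) and 22.7% for the main signal of brain 2. Among regions with at least 5 reads the shares were 7.72% and 3.27% for brain 2, and 1.48% and 7.06% for brain 3. The main-signal library of brain 2 had more regions than that of brain 3 (464383 against 48265), and in both comparisons the larger share was with brain 2. With the main signal of brain 1 the shares were 8.39% for brain 2 and 13.4% for brain 3. Other measures gave no single order. For brain 2, the Jaccard index of covered bases was 4.41% within the brain, 3.86% with the main signal of brain 3 and 8.04% with that of brain 1. For brain 3 it was 9.16% within, 6.42% with brain 2 and 11.2% with brain 1. The fold over shifted regions for brain 2 was 35.9 within, 76.2 with brain 3 and 134 with brain 1. For brain 3 this fold was 186 within, 64.8 with brain 2 and 201 with brain 1. Shared transcripts alone can raise this fold, as for the pairs of brains above. With 2 brains, no exact paired test can reach 0.05, so no p-value is given.

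The 2 mouse CLIP libraries shared far more. Of the 292092 regions of library 1, 74.3% overlapped a region of library 2 (95% Wilson interval 74.2 to 74.5), and of the 307042 regions of library 2, 70.7% overlapped a region of library 1 (70.5 to 70.9). Shifted regions gave 0.601% and 0.571%, a comparison that shared transcripts alone would also exceed. The covered bases had a Jaccard index of 65.3%, and 216916 of 381807 merged regions (56.8%) were found in both libraries. Regions with at least 5 reads were shared in 87.9% on average. Among regions with the same start and end in both libraries, the read numbers had a rank correlation of 0.932 across regions. Of the regions with at least 100 reads, 84.0% and 83.9% had a region of the same start and end in the other library. In the human libraries this share ran from 3.02% to 66.3% among the ordered pairs whose first library had at least 100 such regions.

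**Figure D2:**
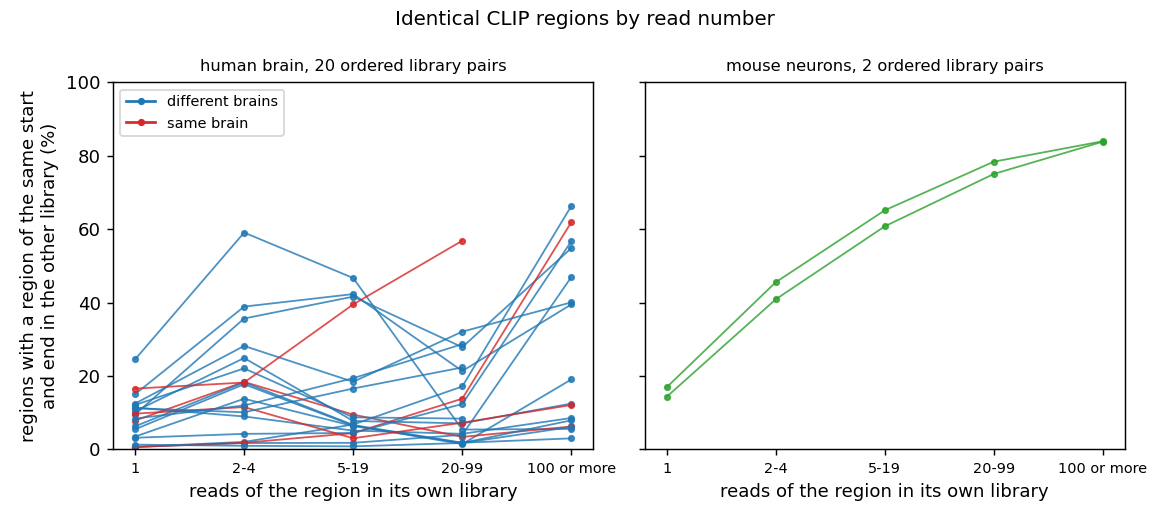
Share of regions that have a region of the same start and end in the other library, in percent, by the number of reads of the region in its own library. Each line is 1 ordered pair of libraries, and classes with at least 100 regions are drawn. In mouse neurons the share rose with the reads to 84.0% and 83.9%, and in human brain the pairs ran from 3.02% to 66.3% in the highest class.

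TAF15 siRNAs were compared with control siRNAs to ask which RNAs change when TAF15 is reduced. The level of the targeted gene was not analysed here, for want of an annotation, so the comparison rests on the labels. Merging the deposited regions of the 6 libraries gave 4100467 consensus regions, of which 196803 passed the expression filter. None passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, where 0 were called, the smallest adjusted p was 0.193, and 9087 (4.62%) had an unadjusted p under 0.05. limma called 1199 regions and DESeq2 called 3807, so the count of 0 depended on the tool, and without the filter edgeR itself called 57363. The regions varied strongly between libraries, with a biological coefficient of variation of 0.979. In counts of 30000 regions simulated at that spread, 0 of 100 regions changed by a log2 fold of 3 were recovered, so the test had little power.

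The 5 regions with the smallest p in each direction did not pass the threshold (adjusted p = 0.193 in edgeR for each). The higher ones were chromosome 4 from 102598949 to 102598963, plus strand (log2 fold change 6.67), and, on the minus strand, chromosome 5 from 132494429 to 132494522 (4.98) and from 21390726 to 21390844 (13.42), chromosome 17 from 88392274 to 88392476 (5.28) and chromosome X from 6738221 to 6738346 (4.12). Of these, 4 had reads in every control library, such as 11, 28 and 20 for the region of chromosome 4, against 3381, 490 and 2094 in the knockdown libraries. The remaining one, chromosome 5 from 21390726, had 0 control reads. The lower ones were chromosome 1 from 24622904 to 24623013 (-15.76), chromosome 10 from 36854671 to 36854812 (-13.95) and chromosome 15 from 76913185 to 76913286 (-12.73) on the minus strand, and chromosome 4 from 154932507 to 154932552 (-13.28) and chromosome 2 from 49626769 to 49626885 (-13.24) on the plus strand. All 5 lower regions had 0 reads in each knockdown library, and the region of chromosome 1 had 6758, 7219 and 7897 in the control libraries. Outside the mitochondrial chromosome, 108 regions had at least 100 reads in every library of 1 group and 0 in the other, 92 of them in the control libraries. For 101 of the 108 (93.5%), the reads of the surrounding 10-kb window differed under 1.5-fold between the groups.

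Reads were therefore also summed over 50-kb windows of each strand, a choice made after the consensus regions had been examined. In edgeR's quasi-likelihood test 456 windows were higher and 87 lower with TAF15 siRNAs, of 30292 tested, at an adjusted p under 0.05. The median log2 fold change was 0.55 among the higher windows and -0.52 among the lower. Of the 456 higher windows, 242 (53.1%) lay in runs of adjacent windows, and none of the 87 lower windows had a called neighbour. The longest runs spanned 450 kb, on the minus strand of chromosome 14 from 93800001 to 94250000 (mean log2 fold change 0.53) and on the plus strand of chromosome 16 from 81200001 to 81650000 (0.56). Runs of 350 kb lay on the minus strand of chromosome 8, from 39300001 to 39650000 (0.69) and from 61050001 to 61400000 (0.63).

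The knockdown libraries stood apart from each other as well as from the controls. On the leading principal component of the windows (48% of the variance), the control libraries lay at -27.14, -28.55 and -19.60, knockdown replicates 1 and 3 at 3.85 and 3.04, and the shallow knockdown replicate 2 at 68.4. Knockdown replicate 3 lay apart on the next component, at -42.15. The number of called windows was not stable. Over 25 other settings it ran from 0 to 2473, and 4 of the 25 stayed within 1.5 times of 543. limma called 0 windows, with 6426 at an unadjusted p under 0.05, and DESeq2 called 1500. Leaving out any single control library left 1 window, as did leaving out knockdown replicate 2, while leaving out knockdown replicate 1 or 3 gave 2473 or 2102. The excess of higher windows was not stable either: 1207 were higher and 1266 lower without knockdown replicate 1, 7 and 23 without both libraries numbered 1, 1391 and 1039 without a filter, and 992 and 508 in DESeq2. With both libraries numbered 1, 2 or 3 left out, 30, 0 and 272 windows were called. The share of windows with an unadjusted p under 0.05 was steadier, at 22.1% with all libraries and 10.1% to 25.7% with libraries left out.

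**Figure D3:**
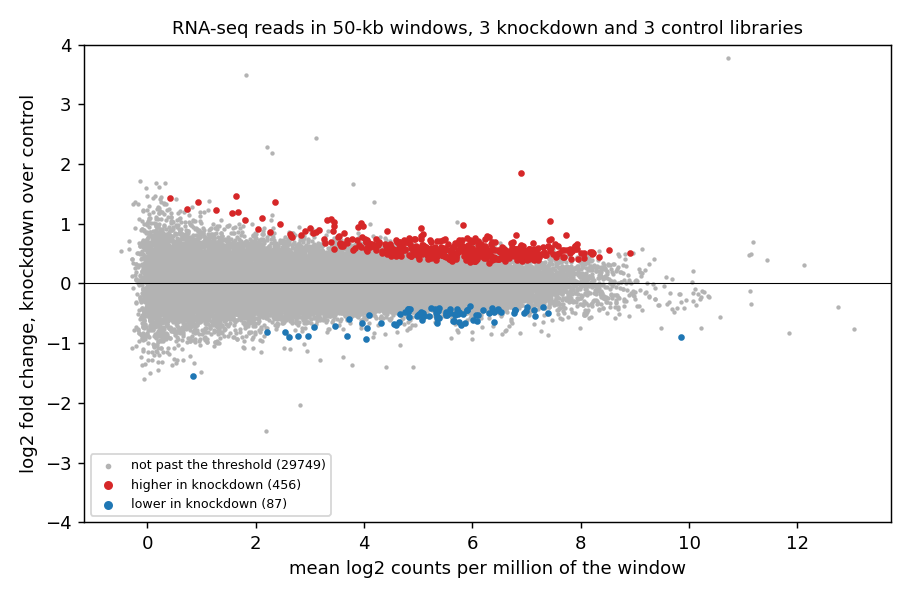
Log2 fold change of each 50-kb window, knockdown over control, against its mean log2 CPM, in 3 knockdown and 3 control libraries. Coloured points are the 456 higher and 87 lower windows past an adjusted p of 0.05 in edgeR.

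Named windows were the 5 with the largest changes in each direction. Chromosome 1 from 88250001 to 88300000, minus strand, had 52.0 ± 2.48 reads scaled to library size (CPM) in control and 190 ± 71.5 in knockdown libraries (SD, n = 3 each; log2 fold change 1.85, SE 0.20, adjusted p = 0.0206 in edgeR). A single region held 90.9% of its reads. The minus-strand windows of chromosome 7 from 68400001 to 68450000 (log2 fold change 1.46), chromosome 3 from 40700001 to 40750000 (1.43) and chromosome X from 142450001 to 142500000 (1.36) were higher, with knockdown means of 4.70, 1.67 and 2.58 CPM. The plus-strand window of chromosome 18 from 28300001 to 28350000 was also higher (1.36), with 99.1% of its reads in 1 region.

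Among the lower windows, chromosome 12 from 54300001 to 54350000, plus strand, had 2.33 ± 0.399 CPM in control and 0.711 ± 0.336 in knockdown libraries (log2 fold change -1.55, SE 0.33, adjusted p = 0.0439 in edgeR). Chromosome 15 from 82950001 to 83000000, plus strand, was the most abundant, at 1195 ± 37.2 against 640.8 ± 230 (log2 fold change -0.90, SE 0.20, adjusted p = 0.0442 in edgeR), and 1 region held nearly all of its reads (99.95%). Chromosome 11 from 103900001 to 103950000, minus strand (-0.93), chromosome 13 from 97750001 to 97800000, minus strand (-0.89), and chromosome 6 from 4450001 to 4500000, plus strand (-0.89), were also lower. Single regions held 79.9%, 97.6% and 18.9% of the reads of these 3 windows.

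**Figure D4:**
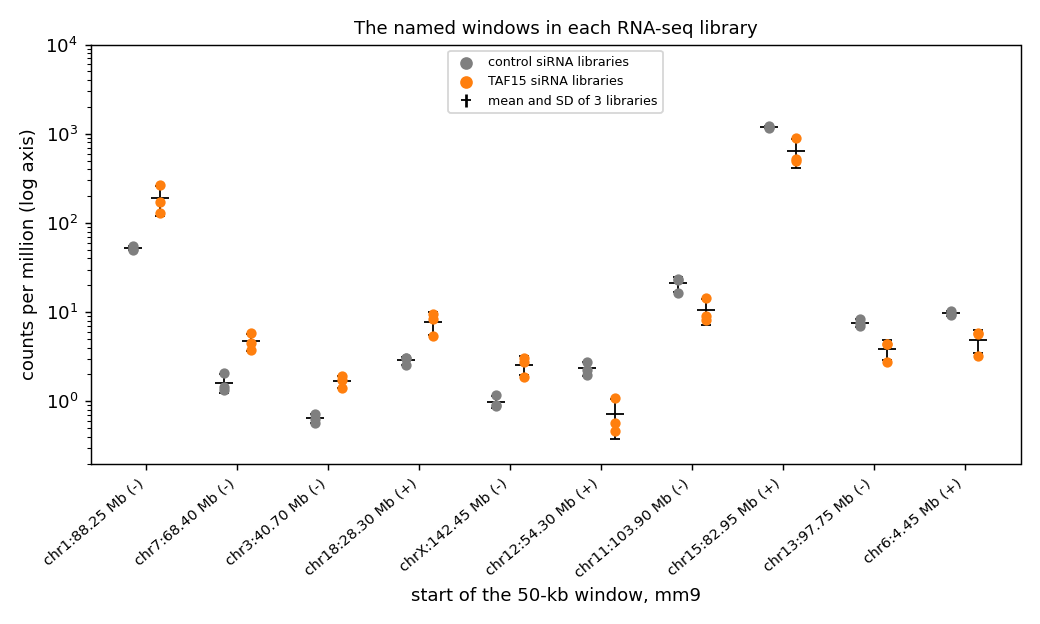
CPM, on a log axis, of the 10 named 50-kb windows in each RNA-seq library. Points are libraries, and bars give the mean and SD of 3 libraries. The window of chromosome 1 rose from 52.0 to 190 CPM, and the window of chromosome 15 went from 1195 to 640.8.

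Mitochondrial RNA made up a larger share of the reads after TAF15 siRNAs. It held 10.4% ± 1.31 of the reads in the 3 knockdown libraries and 6.80% ± 0.0994 in the 3 control libraries, a ratio of 1.53. Every knockdown library (9.48% to 11.9%) lay above every control library (6.69% to 6.87%), a separation of the groups that 10% of splits give by chance. The two-sided exact permutation test gave p = 0.1, the smallest value that 3 libraries against 3 allow. The plus strand of the mitochondrial genome carried the difference (10.3% against 6.69%, exact p = 0.1). On the minus strand the shares were 0.122% ± 0.0398 and 0.115% ± 0.0166, which differed by less than the spread between libraries (exact p = 0.8).

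Mouse CLIP windows were set beside the knockdown change to ask whether bound RNAs respond. Of the 30292 tested windows, 26463 held a CLIP region in both libraries, and their median log2 fold change was 8e-04 against -0.0045 in the other 3829 windows. A camera test with a preset correlation of 0.01 gave p = 0.770, and p = 0.558 with an estimated correlation. A permutation test against 10000 random window sets matched on expression, whose median log2 fold change was -0.0023, gave p = 2e-04, the smallest these sets can give. It treats windows as independent, which camera does not. Because most tested windows were bound, the random sets also redrew many of the bound windows themselves. Bound windows included 452 of the 456 higher and 80 of the 87 lower windows, beside 26463 of all 30292 tested. A window counted as bound with 1 region of any read number in each library, and this count was not matched on expression. In the 3030 windows (10%) with the most CLIP reads per RNA-seq read, a set chosen after the data were seen, the median was 0.07 against -0.01 (camera p = 0.0275, and p = 0.288 with an estimated correlation), so the call was lost.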

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

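The tests of opposite-strand sites and of other splits were chosen after the short stacks had been seen; the test of the surrounding reads was written before its result was seen. All short-stack sites named here were found in the data.

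Mitochondrial reads, which the comparisons of windows leave out, were above the control level in the TAF15 siRNA libraries, at 10.4% ± 1.31 against 6.80% ± 0.0994 of the reads (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). No explanation of this was tested.

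Short stacks of reads, also left out of the window counts, held 24 sites that were present in the knockdown libraries and nearly absent from the control libraries, and 19 sites with the opposite pattern. A site had at least 10 reads in each library of its group and at least 10 times the reads of any library of the other group. The sites were 15 to 21 nt wide. The knockdown sites with the most reads were chromosome 4 from 102598949 to 102598963, plus strand (3381, 490 and 2094 reads in the knockdown libraries), chromosome 15 from 94846032 to 94846046, minus strand (3370, 457 and 2062), and chromosome 11 from 83302464 to 83302478, plus strand (3417, 440 and 1975). The near equal numbers at these 3 places of 15 nt are a pattern that reads of 1 sequence with several equal matches in the genome would leave, so sites need not be independent; sequences were not analysed here. The densest stretch, 17.5 kb on chromosome 11 from 83302462 to 83319946, held 5 knockdown sites at 3 positions. No fixed 50-kb window of another chromosome held more than 2. The other reads of its plus strand, from 83300001 to 83320000, were 40.2 ± 2.10 CPM in control and 46.7 ± 10.9 in knockdown libraries (exact permutation p = 0.5, n = 3 each), so their mean was not lower with TAF15 siRNAs. Whether this stretch lies in the gene targeted by the siRNAs was not analysed here. If it does, these reads show no loss of the targeted RNA. They cannot exclude a loss, since exons and introns were not told apart and the knockdown libraries varied. The level of the targeted gene was not measured in any other way, so each knockdown comparison here rests on the labels.

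Of the 43 sites, 23.3% had a site of the same group on the opposite strand, while 0 of 1327 other short-stack sites, which had at least 10 reads in each library of 1 group, had another of these 1327 there (a count of 0 allows up to 0.225%). No p is given, since sites need not be independent. A change of the surrounding transcripts is argued against for the 13 sites with at least 60 other reads in their 10-kb window. Those reads changed by a median of -0.0728 on the log2 scale in the direction of the stack. The SE of 0.0778 is taken over sites, which need not be independent. The stacks of all 43 sites differed by 5.18 on the log2 scale in unscaled reads, a difference that the choice of sites made large in advance. Reads from the transfected double-stranded siRNAs are a candidate explanation that the pairs on opposite strands leave open, and it was not tested by sequence. The 43 sites compare with at most 6 in the other splits of the 6 libraries, and 10 splits are too few for a share under 0.05. No biological explanation was tested beyond that of the surrounding transcripts.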

How the results depend on the processing

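All settings of the window counts were chosen after seeing the data. So were the addition of the higher-signal libraries and the windows with the most CLIP reads per RNA-seq read. The removal of regions with the start and end of one with at least 10 times the reads in another library was too. The rest were fixed before the data were examined.

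For consensus regions, 12 of 15 alternatives also gave 0 calls, including every fit with libraries left out (0 to 0). limma gave 1199, DESeq2 gave 3807, and no filter gave 57363; the cause was not tested. For 50-kb windows, 4 of 25 alternatives stayed within 1.5 times of 543 calls: RLE scaling (518), upper-quartile scaling (622), shifted windows (644) and the replicate block (798, of which 495 were shared). The others gave 2430 without a filter, 0 with limma, 1500 with DESeq2, 142 with short stacks kept (97 shared), 4 with regions of at least 20 nt and 4 with at least 30 nt, 101 with 10-kb and 0 with 200-kb windows, and, with short stacks kept, 207, 93 and 34 for 10, 2 and 200 kb. With libraries left out the count ran from 0 to 2473. The share of windows with an unadjusted p under 0.05 (22.1%) was 12.01% without a filter and 11.2% in 2-kb windows with short stacks kept. With libraries left out this share was 10.1% to 25.7%, and 20 of its 25 alternatives stayed within 1.5 times.

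The labels do not state whether the replicate numbers pair the libraries. Deviations of same-numbered libraries from their group means correlated at 0.06, -0.04 and -0.01. With 3 libraries per group these values cannot exclude a pairing. With the replicate block, 0 consensus regions, 798 windows, 288 windows with short stacks kept, and 21.6% of windows at an unadjusted p under 0.05 were found. The block kept 9 of the 10 named windows past the threshold and left chromosome 3 from 40700001 at an adjusted p of 0.0547. For bound windows the block left the camera value at 0.770.

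The share between human brains (14.1%) ran from 9.97% to 19.6% with a brain left out, and was 6.92% with at least 5 reads. It was 6.04% without regions that had the start and end of one with at least 10 times the reads in another library. All 7 alternatives moved it by less than its SD of 11.6, which is large. The mouse share (72.5%) went the other way, to 87.9% with at least 5 reads. The higher-signal share of brain 2 (12.2%) was 11.9% at 50% of the shorter region, 7.72% with at least 5 reads and 5.44% without the regions removed in that way. That of brain 3 (10.2%) was 1.48% with at least 5 reads and 5.61% without such regions. For bound windows (camera p = 0.770), the permutation test with matched random sets gave 2e-04. In camera, the 10% of windows with the most CLIP reads per RNA-seq read gave 0.0275 at the preset correlation and 0.288 at an estimated one, so the call was lost. The other 5 alternatives, among them the random sets without matching (0.52), stayed above the threshold. The depth of knockdown replicate 2 and of the main signal of brain 3 limits these comparisons.

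Not run, for want of an annotation or genome: counts over gene bodies, regions over several genes left out, and every alternative of the targeting check, gene lists, exon usage, annotation classes, shared target genes and motifs. Matching on length changes nothing with windows of 1 length.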

Other observations

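The tests of regions with equal start and end, of other splits, of the shallow library, of window borders, of block length and of regions with reads in 1 group were all chosen after their results had been seen.

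Human CLIP libraries held many regions with the same start and end, in a pattern that the mouse libraries lacked. Of the regions with at least 100 reads in the main signal of brain 2, 66.3% had such a region in brain 1, mostly of few reads (median 4), against 5.59% in the opposite direction. In 5 of the 6 library pairs with at least 100 such regions on both sides the directions differed over 2-fold, which carry-over of reads between libraries could produce. Sites shared by the brains and cut at the same bases stay open, since the rank correlations of the read numbers were below 0 in 6 of 10 pairs (median -0.168, against 0.932 in mouse) and reached 0.609 in that same pair of brains 1 and 2. RNA molecules shared by libraries of 1 brain stay open too: the within-brain to between-brain ratio was 0.979 (11.9% against 12.2%), but the within-brain shares ran from 3.81% to 25.4%, and the main signal of brain 3 shared 25.4% with its own brain and at most 13.3% with others.

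The 543 windows past the threshold compare with at most 1 in the other splits of the 6 libraries, and 10 splits are too few for a share under 0.05. Whether the shallow knockdown replicate 2 is the source stays open: without it 17.2% of the windows had an unadjusted p under 0.05, against at most 8.80% in the 9 other splits of the same 5 libraries, but the calls fell to 1, and without both libraries numbered 2 the share was 10.1%. Windows shifted by 25 kb gave 644 calls (497 higher and 147 lower), so the calls did not vanish with this 1 shift of the borders. The shifted windows hold the same reads, so the place of the borders stays open as a source of the count. For single windows the place of the borders stays open as well. Of the called windows, 99.3% (539) had the same direction at an unadjusted p under 0.05 in a shifted window, which holds the same reads. A rise of RNA over long transcribed blocks may contribute, but block length and change correlated above 0.1 in 2 of 3 same-numbered comparisons, and knockdown libraries differed among themselves by as much (-0.449), so it cannot be told apart from differences between libraries.

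Some consensus regions had at least 100 reads in each library of 1 group and 0 in the other. Of these, 93.5% lay in 10-kb windows that differed under 1.5-fold. A region position that moves between libraries would give this, but so would a local change diluted by the window's other reads. The share over all 10-kb windows was not computed, so the explanation stays open. All 10 splits of the 6 libraries, the real one included, called 0 consensus regions in edgeR, where the real split had 9087 at an unadjusted p under 0.05, limma called 1199 and DESeq2 3807. For bound windows, 4 of the 10 splits, the real one included, gave a median difference of at least the real size (0.0133, with 0.0288 the highest other), taken from mean log2 CPM per group, where the edgeR fold changes differ by 0.0053. The 10% of windows with the most CLIP reads per RNA-seq read gave a camera p of 0.0275 at the preset correlation and 0.288 at an estimated one, and other splits went as low as 7.29e-04 at the preset correlation.

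In the first 3 Mb of the mouse chromosomes, the control libraries held 712, 963 and 1006 regions, the knockdown libraries 1044, 375 and 1119, and each mouse CLIP library 4. This stretch was set as the gap region at the start of the chromosomes. Why the RNA-seq libraries held regions there was not tested, which limits trust in their positions.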
